A study of Mus musculus with 6 samples.

How the data were processed

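The series holds RNA sequencing of mouse epidermis from C57BL/6 animals at postnatal day 4, with 3 wt and 3 ARPC4 ko libraries. Per the labels' protocols, skin was digested with trypsin to separate the epidermis, total RNA was extracted with TRIzol, and libraries were made with the TruSeq Stranded mRNA kit and sequenced as single-end reads of 51 bp. The deposited values are counts of reads per Ensembl gene, not normalized. The submitters' processing notes name TopHat2 2.0.12, Bowtie 1.1, HTSeq and the mm10 genome build. The settings of these tools, the strand option used in counting and the annotation release are not given in the sources used here. Without the strand option, reads of a gene and of an overlapping or antisense gene cannot be told apart.

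Each count file held 41214 gene identifiers and, per chromosome, the reads that were not assigned to a gene because they aligned to more than 1 place, overlapped several genes or overlapped none. These unassigned reads stayed out of library sizes and tests. Reads with more than 1 alignment made up 40.9, 40.5 and 32.4% of all reads listed in wt replicates 1 to 3 and 39.4, 37.7 and 35.1% in ko replicates 1 to 3. Those on chromosome 3 alone made up 15.9 to 28.5%. Ambiguous reads made up 0.38 to 0.499% and reads outside genes 0.341 to 0.377%. Genes with close copies therefore have incomplete counts. Gene symbols were taken from the reference table of gene names (40254 identifiers matched) and coordinates, 1-based, from GENCODE release M21 on GRCm38, the same assembly as mm10 (40340 identifiers matched).

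Groups were taken from the genotype label. Replicate numbers came from marks in the titles, with I as replicate 1, II as replicate 2 and Tryp as replicate 3, and the titles of replicates 1 and 2 carry a date, which was treated as a possible collection batch. Nothing in the labels says that the replicates came from separate animals, so p-values measure only the spread between these samples. No replicates agreed within sampling noise (chi-square per degree of freedom between 24.4 and 105.5 within groups), so each counted as 1 sample. Depth ran from 17561294 to 22659511 counts in genes per library. Counting error is small beside the spread between replicates for abundant genes, and large for genes of under 1 CPM.

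The main test was edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (13704 genes, 13643 with a symbol) and scaled by TMM. They were fitted by glmQLFit with robust estimation and the method's current settings, under which the fit estimates its own dispersion. Differences were tested by glmQLFTest with group as the only factor, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Log2 fold changes are ko over wt, and the SE is the size of the log2 fold change over the square root of the F statistic. CPM are counts over the TMM-scaled library size, given as mean ± SD of 3 libraries.

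The 34 gene lists, the rule for named genes, the main test and the alternatives, except those said to have been added, were chosen before the data were examined. The rule named the Arp2/3 subunits, Nfe2l2 and Keap1, and the 10 genes in each direction with the largest change among those past the threshold with a mean of at least 5 CPM and groups that did not overlap, leaving out predicted and sex-linked genes. It also named the 5 genes with the smallest p, and from each list up to 4 members with the smallest p, all members of lists of up to 10 and any member of at least 1000 CPM. No gene was lower past the threshold. The lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists. They were also tested with an estimated correlation and with fry. Each list has a count over all genes and one adjusted over the list alone.

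The other analyses chosen beforehand were scaling by DESeq2 size factors, by upper quartiles or by total counts, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 on all genes with its own filter, limma-voom, the older quasi-likelihood fit, a fit that was not robust, a replicate block, a collection covariate, the dated libraries alone, a threshold of 0.01, a minimum change of 2-fold, and leaving out each library in turn. Added after seeing the data were the mean of the basal genes as a covariate, sex from Xist and Ddx3y as a covariate, and leaving out the libraries at both ends of the first principal component.

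The tests were checked on simulated counts with the means and library sizes of the real data, in which 200 of 13532 genes were changed. edgeR recovered 24% of genes changed 2-fold and 93% of those changed 8-fold, with 12 false calls among 129. DESeq2 recovered 45 and 93% with 51 false among 189, and limma-voom 22 and 94% with 9 false among 125. A simulated list of 30 genes changed 2-fold gave a camera p of 1.13e-35, a p of 0.000312 with an estimated correlation and a fry p of 0.000116, among 13508 genes. An unchanged list gave 0.307, 0.31 and 0.025. The simulated genes were drawn independently of each other. The check therefore does not cover lists whose genes correlate, with estimates of up to 0.977 for the basal list. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.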

Results

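Messenger RNA was sequenced from the epidermis of C57BL/6 mice at postnatal day 4, after the skin had been treated with trypsin. The series title names the loss of the Arp2/3 complex, which nucleates branched actin filaments, in the epidermis, together with a psoriasis-like disease and hyperactivation of the transcription factor Nrf2. The 6 libraries fell into 2 groups, with 3 from wild type (wt) and 3 from ARPC4 knockout (ko) epidermis. Replicates 1 and 2 of each group carried a date in their titles and replicate 3 did not. The counts assigned to genes summed to 22659511, 20586062 and 19532675 in wt replicates 1 to 3. They summed to 20745246, 18502944 and 17561294 in ko replicates 1 to 3. Xist, made from the inactive X chromosome, and the Y-linked Ddx3y showed that both sexes were present in each group. Ddx3y lay at 92.1 and 95.2 CPM (TMM-scaled) in wt replicates 1 and 2 and at 121.3 CPM in ko replicate 2. Xist lay at 578.7, 542.9 and 507.8 CPM in wt replicate 3 and ko replicates 1 and 3. The sexes were therefore not balanced between the groups. Some Ddx3y, 1.22 CPM, was also counted in wt replicate 3, against 0 in ko replicates 1 and 3.

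The targeted gene was examined first. Arpc4 (ENSMUSG00000079426, chromosome 6, 113378115 to 113390448, plus strand, mm10) encodes a core subunit of the complex. It was measured at 72.6, 82.5 and 73.1 CPM in wt replicates 1 to 3 and at 67.6, 65.6 and 64.5 CPM in ko replicates 1 to 3. Every ko library lay below every wt library, with group means of 65.9 ± 1.56 and 76.1 ± 5.61 CPM (SD, n = 3). The log2 fold change of -0.21 (SE 0.10, 95% interval -0.45 to 0.04) did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.469). The labels do not say which part of the gene was deleted, and reads from remaining exons are counted, so this level does not check the deletion or the protein. Reads that overlapped several genes were left out. On chromosome 6 they made up 0.0162% of all reads in wt and 0.0118% in ko, with every ko library below every wt library. Which genes they overlapped is not given. Of the 9 measured Arp2/3 subunits 0 passed with edgeR over all genes and 0 when adjusted over the list alone. At an unadjusted p under 0.05 there was 1, Actr2, and DESeq2 called 0. Their log2 fold changes ran from -0.25 for Arpc1a to 0.33 for Arpc1b, with 0.33 for Actr2, 0.16 for Actr3, 0.13 for Arpc5, -0.13 for Arpc5l, 0.12 for Arpc2 and 0.10 for Arpc3. The list of 20 measured activators and regulators of the complex had a median of -0.02 (camera adjusted p = 0.576), and the 9 subunits a median of 0.12 (camera adjusted p = 0.625).

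The comparison of ko with wt asked which transcripts differed between the 2 genotypes of the labels. Of 13704 genes tested, 30 rose in ko and 0 fell (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p between 0.0359 and 0.0461). Among those of the 30 with at least 5 CPM, the largest rises belonged to the epithelial cytokine Tslp, the keratins Krt6b and Krt16 and the antimicrobial proteins S100a8 and S100a9. The chemokine receptor Cxcr2, the cornified envelope precursors Sprr2b, Sprr2d and Sprr2e and the peroxidase Lpo were the others. The smallest p belonged to Lpo (ENSMUSG00000009356, chromosome 11, 87806428 to 87828289), which rose from 2.98 ± 0.933 to 55.4 ± 13.1 CPM (SD, n = 3; log2 fold change 4.22, SE 0.30, adjusted p = 0.0359). The next smallest belonged to Nat8l, an N-acetylaspartate synthase (2.0, SE 0.17), the protease inhibitor Serpinb3c (3.36, SE 0.30), the pseudogene Gm8080 (2.06, SE 0.20) and the VEGF receptor Flt1 (4.38, SE 0.42), each with an adjusted p of 0.0407. In all 30 genes every ko library lay above every wt library, and 10 of the 30 lie on chromosome 3, which carries the Sprr and S100 genes. At an unadjusted p under 0.05 there were 1094 higher and 720 lower genes, and in 2652 genes the groups did not overlap. The latter are 19.4% of those tested, against 10% by chance. Splits of the libraries that mixed the genotypes gave up to 2203 genes at an unadjusted p under 0.05, against 1814 for the real groups. DESeq2, with its own filter on low counts, called 650 genes (431 higher, 219 lower), including the 30. Of its calls 617 (398 higher, 219 lower) were among the genes tested with edgeR, on which limma-voom called 0 (1748 at an unadjusted p under 0.05). On simulated counts 51 of 189 DESeq2 calls were false, against 12 of 129 for edgeR, so the DESeq2 counts here and below may hold many false calls. With the dated or undated title as a covariate edgeR called 709 genes (438 higher, 271 lower), again including the 30. Among the 4 dated libraries alone it called 227 (160 higher, 67 lower), of which 18 were among the 30. The undated libraries, 1 per group, allow no test. With edgeR 0 genes passed without wt replicate 1, 2 or 3 or without ko replicate 2, when 1229 to 2350 genes had an unadjusted p under 0.05 and DESeq2 called 238 to 805 and limma-voom 0. Without ko replicate 1 there were 30, of which 2 were lower and 19 were among the original 30, and without ko replicate 3 there were 64.

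**Figure D1:**
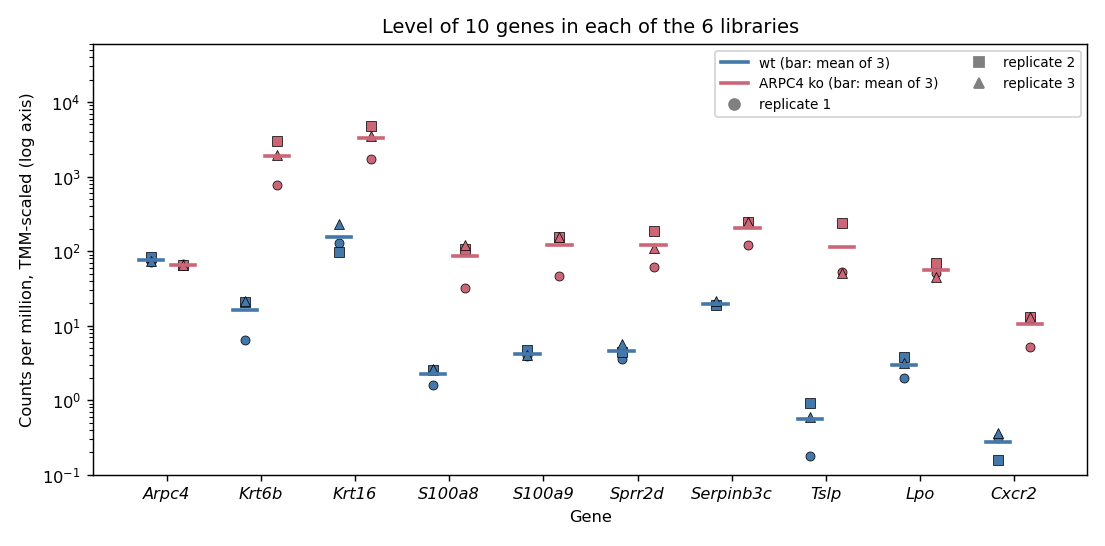
Level of 10 genes in each of the 6 libraries, in TMM-scaled CPM on a log axis, with wt in blue, ARPC4 ko in red, a marker shape for each replicate and a bar at each group's mean of 3. Arpc4 lies at 64.5 to 82.5 CPM in all libraries, while Krt6b lies at 6.34 to 21.1 CPM in wt and at 763.8 to 3006 CPM in ko.

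Keratins of wounded and hyperproliferative epidermis were among the genes called higher in ko. Krt6b (ENSMUSG00000023041, chromosome 15, 101676023 to 101680287, minus strand) rose 118-fold, from 16.1 ± 8.46 to 1904 ± 1122 CPM (SD, n = 3; log2 fold change 6.89, SE 0.76, adjusted p = 0.0407). Krt16 (ENSMUSG00000053797, chromosome 11, 100246091 to 100248902, minus strand) rose 21.9-fold, from 152.3 ± 71.8 to 3337 ± 1515 CPM (4.45, SE 0.52, adjusted p = 0.0458). Krt6a stood at 114.9 ± 49.3 and 1332 ± 594.7 CPM and Krt17 at 1609 ± 299.9 and 2432 ± 963.7 CPM, with adjusted p of 0.0658 and 0.488 over all genes (edgeR, Benjamini-Hochberg). Of the 4 keratins 2 rose over all genes and 3 (Krt6a, Krt6b, Krt16) when adjusted over the list alone. The list was called higher by camera (median log2 fold change 3.99, adjusted p = 5.75e-06; adjusted p = 0.145 with an estimated correlation). Small proline-rich and Lce3 genes encode proteins of the cornified envelope. Of 20 measured members 6 rose over all genes and 18 when adjusted over the list alone. Sprr2d rose from 4.61 ± 1.08 to 120.7 ± 64.1 CPM, Sprr2b from 0.586 ± 0.332 to 17.5 ± 8.9 CPM and Sprr2e from 0.867 ± 0.259 to 19.4 ± 9.41 CPM. Sprr1b rose from 38.5 ± 6.57 to 323.4 ± 147.9 CPM. The median log2 fold change of this list was 4.15 (camera adjusted p = 6.49e-23; adjusted p = 0.124 with an estimated correlation). The Krt6 pair, Krt16 and Krt17, and the Sprr2 genes have close copies, and reads with more than 1 alignment were not assigned to a gene, so their levels are uncertain. The single-gene calls were lost without any of wt replicates 1, 2 and 3 or ko replicate 2, when 0 genes passed with edgeR (238 to 805 with DESeq2, 1229 to 2350 at an unadjusted p under 0.05). Endothelial markers were also higher in the ko libraries, with a list mean 2.11 ± 0.28 log2 (SE) higher, and fibroblast markers with one 1.63 ± 0.47 higher. Within ko the order of the libraries differed. The keratin list means were 10.1, 11.4 and 11.3 log2 CPM in ko replicates 1 to 3. The endothelial ones were 1.36, 1.45 and 0.60, and the fibroblast ones 4.95, 5.15 and 4.00.

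Alarmins and antimicrobial genes known to be raised in psoriatic skin were measured for the question the series title raises. S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035, plus strand) rose 38.8-fold, from 2.24 ± 0.568 to 86.8 ± 48.0 CPM (SD, n = 3; log2 fold change 5.28, SE 0.57, adjusted p = 0.0407). Its partner S100a9 rose 28.2-fold, from 4.23 ± 0.449 to 119.1 ± 62.5 CPM (4.82, SE 0.50, adjusted p = 0.0407; edgeR, Benjamini-Hochberg). Serpinb3c rose from 19.8 ± 1.24 to 204.0 ± 72.6 CPM. The stefins, inhibitors of cysteine proteases, had the highest levels on the list. Stfa3 stood at 2636 and 5018 CPM (log2 fold change 0.93, adjusted p = 0.178), BC100530 at 1061 and 2210 CPM (1.06, adjusted p = 0.15) and Stfa2 at 168.1 and 677.9 CPM (2.01, adjusted p = 0.0593). Of 22 measured members 3 rose over all genes, and 14 were higher when adjusted over the list alone. The 1 that was lower over the list alone, Vnn1 (-1.56), a pantetheinase, was named after its values were seen. The stefin and Serpinb3 genes also have close copies, so their levels are uncertain. The list was called higher by camera (median log2 fold change 1.1, adjusted p = 8.72e-08; adjusted p = 0.201 with an estimated correlation). Among 17 measured cytokines and chemokines 1 rose over all genes and 6 were higher when adjusted over the list alone. Tslp (ENSMUSG00000024379, chromosome 18, 32815383 to 32819797, plus strand), a cytokine of barrier epithelia, rose from 0.557 ± 0.365 to 113.1 ± 105.3 CPM (7.69, SE 0.93, adjusted p = 0.0458), with 52.9, 234.7 and 51.6 CPM in ko replicates 1 to 3. The alarmin Il33 stood at 4.35 ± 3.03 and 36.7 ± 18.8 CPM (3.06, SE 0.65, adjusted p = 0.115), Il1a at 0.65 (adjusted p = 0.169) and Il1f9, the gene of IL-36 gamma, at 0.75 (adjusted p = 0.179). The cytokine list had a median of 1.1 (camera adjusted p = 1.59e-06; adjusted p = 0.124 with an estimated correlation). That median was 0.61 without ko replicate 3 and 0.71 among the dated libraries, both still called. In the same ko libraries the list means of endothelial, fibroblast and macrophage markers were higher by 2.11 ± 0.28, 1.63 ± 0.47 and 0.99 ± 0.37 log2 (SE). The calls of single genes named here were lost without any of wt replicates 1, 2 and 3 or ko replicate 2, when 0 genes passed with edgeR (238 to 805 with DESeq2, 1229 to 2350 at an unadjusted p under 0.05).

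Targets of Nrf2, the transcription factor of the response to electrophiles and oxidants, went both ways in the fixed list. That list holds mainly genes of antioxidant defense, detoxification and related metabolism. The keratin, small proline-rich and alarmin genes above are not in it and were not tested as Nrf2 targets. Of 36 measured targets 0 passed with edgeR over all genes, while 6 were higher and 3 lower at an unadjusted p under 0.05 and DESeq2 called 3 higher and 2 lower. When adjusted over the list alone 5 were higher and 2 lower. The cystine transporter Slc7a11 stood at 4.98 ± 0.696 CPM in wt and 18.9 ± 7.92 CPM in ko (log2 fold change 1.92, SE 0.31, adjusted p = 0.0798 over all genes by edgeR and Benjamini-Hochberg). The glutathione transferase Gsta4 stood at 2.85 ± 0.505 and 13.7 ± 8.95 CPM (2.26, SE 0.53, adjusted p = 0.14). The other 3 on the higher side, the aldo-keto reductase Akr1b8 (2.55), sulfiredoxin Srxn1 (0.77) and the carbonyl reductase Cbr3 (0.52), were named after their values were seen. The microsomal glutathione transferase Mgst1 stood at 49.6 ± 4.33 and 30.7 ± 2.76 CPM (-0.69, SE 0.12, adjusted p = 0.0852). Osgin1, an oxidative stress-induced growth inhibitor, stood at 6.77 ± 0.567 and 2.78 ± 1.0 CPM (-1.28, SE 0.28, adjusted p = 0.127). Commonly used targets, chosen after their values were seen, had log2 fold changes of -0.14 for Nqo1, -0.25 for Hmox1, -0.01 for Gclc, 0.10 for Gclm and -0.14 for Txnrd1. The list had 13 members above 0 and 23 below, a median of -0.14 and a mean of 0.03. Camera placed it lower without a call (adjusted p = 0.279; adjusted p = 0.429 with an estimated correlation; fry adjusted p = 0.546). Tested for change in either direction, the list had a fry adjusted p of 0.0146. Nfe2l2 (ENSMUSG00000015839, chromosome 2, 75675513 to 75704641, minus strand) encodes Nrf2. It stood at 48.6 ± 5.44 and 64.7 ± 4.17 CPM, with every ko library above every wt library (0.41, SE 0.12, adjusted p = 0.222). Keap1, its inhibitor, stood at 40.1 ± 1.91 and 36.5 ± 1.70 CPM (-0.13, adjusted p = 0.669). Nrf2 is regulated mainly through protein stability, which was not measured here.

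**Figure D2:**
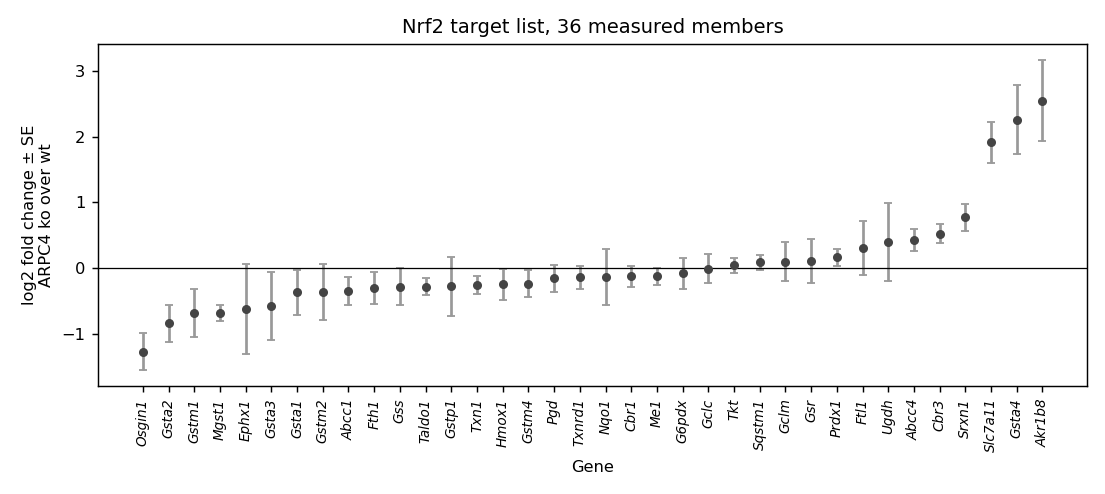
Log2 fold change of ARPC4 ko over wt with its SE for the 36 measured Nrf2 target genes, in order of value, from 3 libraries per group. Of these 23 lie below 0, down to -1.28 for Osgin1, and 13 above, up to 2.55 for Akr1b8.

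Basal and proliferation genes varied more between replicates than between groups. Basal keratinocyte genes, such as the keratins of the proliferating layer, had list means of 7.61, 5.18 and 8.11 log2 CPM in wt replicates 1 to 3 and 6.48, 6.74 and 8.36 in ko replicates 1 to 3. Krt5 lay at 3424, 846.0 and 4301 CPM in wt and at 1292, 1677 and 5443 CPM in ko. Of 16 basal genes 0 passed with edgeR over all genes or the list alone, while 1, the hyaluronan receptor Cd44 (log2 fold change 0.89), was called by DESeq2 and at an unadjusted p under 0.05. The list's median was -0.04, its mean 0.04 and its camera direction up without a call (adjusted p = 0.568). Without wt replicate 2 it was called lower (median -0.52, adjusted p = 0.0297). All 30 proliferation genes had values above 0 (median 0.34), and 0 passed with edgeR, with DESeq2 or at an unadjusted p under 0.05 (camera adjusted p = 0.241). Their list was called higher without wt replicate 3 (0.92, adjusted p = 0.0019), ko replicate 1 (0.61, adjusted p = 0.00712) or ko replicate 2 (0.58, adjusted p = 0.0374), and with the collection as a covariate (0.26, adjusted p = 0.0241). Without ko replicate 3 its median was -0.42 (adjusted p = 0.153), and without wt replicate 2 it was 0.00 (adjusted p = 0.298), both uncalled. Of 40 suprabasal and terminal differentiation genes 0 passed with edgeR over all genes or the list alone, while 1 was higher and 2 lower at an unadjusted p under 0.05 and DESeq2 called 1 higher and 1 lower (median -0.01, mean 0.01, camera adjusted p = 0.755). Rptn was the higher and Lce1m and Krt77 the lower ones at the unadjusted p. Krt1 stood at 42200 and 55350 CPM, Krt10 at 42670 and 51910 CPM and loricrin (Lor) at 13200 and 8524 CPM, with log2 fold changes of 0.39, 0.28 and -0.63 and adjusted p of 0.749, 0.835 and 0.471. The largest difference there was in repetin (Rptn), a cornified envelope protein, at 97.3 ± 40.2 and 1065 ± 926.3 CPM (log2 fold change 3.45, SE 0.67, adjusted p = 0.0971). Without wt replicate 3 this list was called lower (-0.18, adjusted p = 0.0474). Several of its members, among them Lce1 genes, loricrin and Hrnr, lie on chromosome 3. Reads with more than 1 alignment there made up 15.9 to 28.5% of all reads and were not assigned to a gene. Which genes they came from is not given, so the levels of members with close copies or repeats are uncertain. Of 27 barrier lipid genes 0 passed with edgeR over all genes, while 3 were lower and 1 higher at an unadjusted p under 0.05, and 3 were lower with DESeq2 and when adjusted over the list alone. The list-alone ones were the ceramide synthase Cers4 (68.3 ± 0.58 and 30.9 ± 9.77 CPM; -1.14, adjusted p = 0.105), the fatty acid hydroxylase Fa2h (161.9 ± 12 and 62.9 ± 22.8 CPM; -1.36, adjusted p = 0.108) and the elongase Elovl6 (-0.64, adjusted p = 0.157). The lipid list as a whole had a median of -0.14 (camera adjusted p = 0.0964). It was called lower without wt replicate 3 (-0.34, adjusted p = 0.000461) or ko replicate 2 (-0.28, adjusted p = 0.00169), with DESeq2 (-0.17, adjusted p = 0.0373) and among the dated libraries (-0.16, adjusted p = 0.0304). Sebocyte markers moved the same way, with a list mean that differed by -1.14 ± 0.24 log2 (SE) in the ko libraries. The 27 junction and desmosome genes, with desmoplakin (Dsp) at 7616 and 9110 CPM, had a median of 0.13 (camera adjusted p = 0.576), and 0 passed with edgeR or DESeq2 (1 higher and 1 lower at an unadjusted p under 0.05). The libraries at the ends of the first principal component, which held 50.7% of the variance, were wt replicate 2 at -64.2 and ko replicate 3 at 62.6. With both left out, a choice made after seeing the data, edgeR called 294 genes (166 higher, 128 lower). The basal list (-1.54) and the proliferation list (-0.71) were then called lower, and the suprabasal list (0.35) and the lipid list (0.28) higher.

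**Figure D3:**
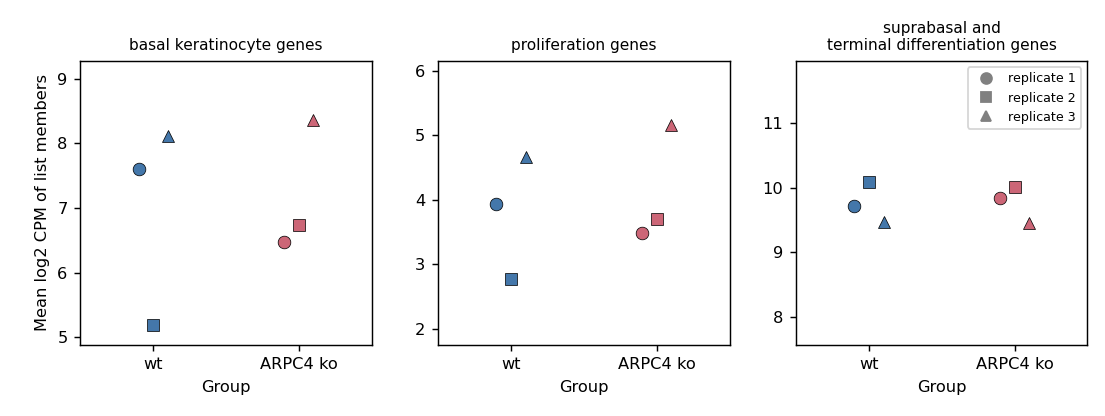
Mean log2 CPM of the measured basal keratinocyte, proliferation and suprabasal genes in each of the 6 libraries, with a marker shape for each replicate and wt in blue and ARPC4 ko in red. The basal genes run from 5.18 to 8.11 in wt and from 6.48 to 8.36 in ko, and the axes of the panels share a span but not a range.

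In lists of growth factor, stress, interferon and actin genes 0 members passed with edgeR over all genes, and the counts by other tools follow for each. The EGFR ligand Hbegf stood at 76.8 ± 12.1 and 172.3 ± 31.3 CPM (log2 fold change 1.16, adjusted p = 0.0688), amphiregulin (Areg) at 1.27 (adjusted p = 0.0782) and epiregulin (Ereg) at 1.13 (adjusted p = 0.0822; edgeR, Benjamini-Hochberg). These were the 3 of 14 growth factor genes that were higher when adjusted over the list alone, and the ligand betacellulin (Btc, -0.97, adjusted p = 0.217) was the 1 that was lower. DESeq2 called 3 higher and 1 lower, and 6 were higher and 1 lower at an unadjusted p under 0.05. That list was called higher (median 0.42, camera adjusted p = 0.0401; adjusted p = 0.429 with an estimated correlation). It was not called without wt replicate 3 (0.25, adjusted p = 0.144), without ko replicate 3 (0.12, adjusted p = 0.209), among the dated libraries (adjusted p = 0.314), with the basal gene level as a covariate (adjusted p = 0.189) or with both end libraries left out (0.27, adjusted p = 0.297). The 21 ATF4 and endoplasmic reticulum stress genes include the amino acid transporter Slc7a5 (0.65, adjusted p = 0.184) and asparagine synthetase Asns (0.51, adjusted p = 0.195). They were called higher as a list (median 0.28, camera adjusted p = 0.00662; adjusted p = 0.429 with an estimated correlation), with 0 members called by DESeq2 and 7 higher and 1 lower at an unadjusted p under 0.05. The list was not called without wt replicate 3 (adjusted p = 0.151), without ko replicate 2 (adjusted p = 0.0506) or among the dated libraries (adjusted p = 0.128). The 20 interferon-stimulated genes were called higher, with a median of 1.21 (camera adjusted p = 0.000791; adjusted p = 0.632 with an estimated correlation). Mx1 stood at 1.78 and Bst2 at 1.62, but Irf7, a regulator of interferon, at -1.25 (adjusted p = 0.159). DESeq2 called 1 higher and 1 lower, and 6 were higher and 1 lower at an unadjusted p under 0.05. In the same libraries the list means of endothelial, fibroblast, macrophage and Langerhans cell markers were higher in ko by 2.11 ± 0.28, 1.63 ± 0.47, 0.99 ± 0.37 and 0.58 ± 0.43 log2 (SE). The interferon call was lost without ko replicate 3 (0.35, adjusted p = 0.0717) and with both end libraries left out (0.23, adjusted p = 0.579). Of 25 actin and SRF-linked genes 2 were higher when adjusted over the list alone, the tropomyosin Tpm2 (1.23, adjusted p = 0.115) and the LIM protein Fhl2 (0.47, adjusted p = 0.13). DESeq2 called 2 higher and 1 lower, and 5 were higher and 2 lower at an unadjusted p under 0.05. Actb and Actg1 stood at -0.25 and -0.17, and the list was not called (median 0.19, camera adjusted p = 0.165). The 20 immediate-early and heat-shock genes that tissue dissociation can induce were not called (median 0.14, camera adjusted p = 0.187), with 1 higher when adjusted over the list alone and by DESeq2, Ier3 (0.78). Fos and Egr1 stood at 0.15 and 0.14, and 3 members were higher and 1 lower at an unadjusted p under 0.05. The 18 p53 targets were not called either (median 0.02, camera adjusted p = 0.905), with 0 called by DESeq2 and 3 higher and 1 lower at an unadjusted p under 0.05.

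Markers of vessels and of the dermis were higher in ko. All 11 measured endothelial markers were higher when adjusted over the list alone. Over all genes 1, Flt1, rose, from 0.439 ± 0.0836 to 9.25 ± 3.85 CPM (SD, n = 3). Cdh5, the cadherin of endothelial junctions, stood at 0.432 ± 0.146 and 3.54 ± 1.57 CPM (log2 fold change 3.04, SE 0.50, adjusted p = 0.0822; edgeR, Benjamini-Hochberg), Robo4 at 3.75 (adjusted p = 0.067) and Pecam1 at 1.75 (adjusted p = 0.0941). The list had a median of 2.62 (camera adjusted p = 7.23e-13; adjusted p = 0.124 with an estimated correlation). None of the 11 reached 5 CPM on average in wt. In the ko libraries the reads of Flt1 were 1.49, 1.71 and 7.68 times those of Cdh5. All 18 fibroblast and dermal matrix markers had values above 0 and 14 were higher when adjusted over the list alone. Over all genes 0 passed with edgeR, 14 were higher at an unadjusted p under 0.05 and 10 were called by DESeq2. The collagen Col5a1 stood at 9.42 ± 2.26 and 23.6 ± 7.18 CPM (1.32, adjusted p = 0.121) and fibrillin Fbn1 at 2.95 ± 0.561 and 15.7 ± 9.82 CPM (2.41, adjusted p = 0.146). The list had a median of 1.94 (camera adjusted p = 2.07e-09; adjusted p = 0.26 with an estimated correlation). The list of Schwann cell and nerve markers was called higher (median 0.70, camera adjusted p = 0.0135; adjusted p = 0.4 with an estimated correlation). That call was lost without wt replicate 2 (0.59, adjusted p = 0.0718) and with both end libraries left out (adjusted p = 0.243), and the median was 1.69 without a filter on low counts. The call of Flt1 was lost without any of wt replicates 1, 2 and 3 or ko replicate 2, when 0 genes passed with edgeR (238 to 805 with DESeq2, 1229 to 2350 at an unadjusted p under 0.05).

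Markers of neutrophils, macrophages, Langerhans cells, mast cells and T cells were measured as separate lists. Of 13 neutrophil markers 3 were measured, and 2 of them rose over all genes and when adjusted over the list alone. These were Cxcr2 (chromosome 1, 74153989 to 74161246, plus strand), from 0.277 ± 0.105 to 10.5 ± 4.67 CPM, and histidine decarboxylase Hdc (log2 fold change 4.28, SE 0.59, adjusted p = 0.0458 by edgeR and Benjamini-Hochberg). The list was called higher (median 4.28, camera adjusted p = 0.000174; adjusted p = 0.124 with an estimated correlation), and its median was 0.73 without a filter on low counts. Cxcr2 had 18 reads in the wt and 578 in the ko libraries together, while in the ko libraries the neutrophil markers Ly6g, Retnlg, Csf3r, Mmp8 and Clec4d had 0, 6, 35, 0 and 18 reads. The calls of Cxcr2 and Hdc were lost without any of wt replicates 1, 2 and 3 or ko replicate 2, when 0 genes passed with edgeR (238 to 805 with DESeq2, 1229 to 2350 at an unadjusted p under 0.05). Of 13 macrophage and monocyte markers 1 was higher when adjusted over the list alone, the mannose receptor Mrc1 (2.65, SE 0.38, adjusted p = 0.0637). The list was called higher (median 0.84, camera adjusted p = 6.03e-05; adjusted p = 0.397 with an estimated correlation), with medians of 0.47 without wt replicate 1, 1.54 without wt replicate 3 and 1.6 among the dated libraries. The 11 Langerhans and dendritic cell markers were called higher (0.49, camera adjusted p = 0.00615; adjusted p = 0.632 with an estimated correlation). They were not called without wt replicate 1 (0.25, adjusted p = 0.0768), ko replicate 1 (0.33, adjusted p = 0.0765) or both end libraries (adjusted p = 0.19). Their median was 0.94 without wt replicate 3, 0.79 without ko replicate 2, 0.81 among the dated libraries and 0.18 with sex as a covariate. Of 8 mast cell markers 3 were measured, while Cpa3, Mcpt4, Tpsb2, Tpsab1 and Ms4a2 did not pass the low-count filter. Of the 3, the prostaglandin synthase Hpgds (1.08, adjusted p = 0.0793) and Kit (0.88, adjusted p = 0.184) were higher when adjusted over the list alone. The 3 markers had a median of 1.08 (camera adjusted p = 0.00463, and adjusted p = 0.194 with an estimated correlation). Their median was 1.8 without wt replicate 2, 2.7 without wt replicate 3, 2.25 without ko replicate 3, 3.15 among the dated libraries, 2.3 without both end libraries and 1.91 without a filter on low counts. The 14 T cell markers were not called (-0.18, camera adjusted p = 0.104) except without ko replicate 1, where they were lower (-0.84, adjusted p = 0.000188).

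Sebocyte markers were lower in ko. All 8 measured markers had values below 0 and 7 were lower when adjusted over the list alone. Over all genes 0 passed with edgeR, 7 were lower at an unadjusted p under 0.05 and 6 were called by DESeq2. The desaturase Scd1 stood at 949.8 ± 56.7 and 435.7 ± 105.2 CPM (log2 fold change -1.12, SE 0.21, adjusted p = 0.0947). Scd3 stood at 99.9 ± 16.6 and 32.0 ± 11.4 CPM (-1.64, SE 0.29, adjusted p = 0.0879) and the fatty acyl reductase Far2 at 217.3 ± 16.1 and 83.9 ± 27.7 CPM (-1.37, SE 0.25, adjusted p = 0.0944; edgeR, Benjamini-Hochberg). The list was called lower (median -1.10, camera adjusted p = 1.01e-08; adjusted p = 0.201 with an estimated correlation). Of 29 hair follicle genes 26 had values below 0 and 0 passed with edgeR or DESeq2 (5 lower at an unadjusted p under 0.05). The list was called lower (median -0.42, camera adjusted p = 0.0003; adjusted p = 0.429 with an estimated correlation), with the hair keratins Krt33b at -1.58 and Krt83 at -1.40. That call was lost without wt replicate 2 (-0.13, adjusted p = 0.197) and without both end libraries (-0.05, adjusted p = 0.534), and the median was -0.74 without wt replicate 3. All 10 melanocyte markers had values above 0, among them dopachrome tautomerase Dct (0.52, adjusted p = 0.264). Their list was called higher (median 0.54, camera adjusted p = 0.00112; adjusted p = 0.429 with an estimated correlation). It was not called without wt replicate 3 (adjusted p = 0.065) or among the dated libraries (0.28, adjusted p = 0.106), and its median was 0.3 without ko replicate 3. Of 4 Merkel cell markers the keratins Krt8 (-1.61) and Krt18 (-0.98) were lower and the ion channel Piezo2 (1.26) higher when adjusted over the list alone (median 0.04, mean -0.07, camera adjusted p = 0.615). Without a filter on low counts the median was -1.07 for the Merkel cell list (adjusted p = 0.177), 0.68 for the adipocyte list (adjusted p = 0.831) and 1.59 for the muscle list (adjusted p = 0.166), all uncalled. Of 7 adipocyte markers 1, the lipid regulator Pparg (-1.23, adjusted p = 0.0941), was lower when adjusted over the list alone (median 0.07, mean 0.20, camera direction down, adjusted p = 0.536). This list was called higher without both end libraries (1.43, adjusted p = 0.0374). The 6 erythroid genes (median -0.30, camera adjusted p = 0.451), the 3 muscle markers (0.68, adjusted p = 0.576) and the 5 sex-linked genes (-0.92, adjusted p = 0.174) were not called. The muscle markers were called without ko replicate 3 (1.4, adjusted p = 0.04997), and the sex-linked genes without ko replicate 2 (-9.88, adjusted p = 0.00316), when no male ko library is left, and with sex as a covariate (-0.22, adjusted p = 0.00816). Of the 34 lists camera called 15 higher and 2 lower. Of the 17, 0 held with an estimated correlation (adjusted p from 0.124 to 0.632), while 8 held with fry, which tests whether the genes of a list move one way on balance. Those lost with fry were the fibroblast (adjusted p = 0.0783), macrophage (0.116), growth factor (0.116), Schwann cell (0.116), ATF4 (0.15), melanocyte (0.159), hair follicle (0.437), Langerhans cell (0.449) and interferon (0.45) lists.

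**Figure D4:**
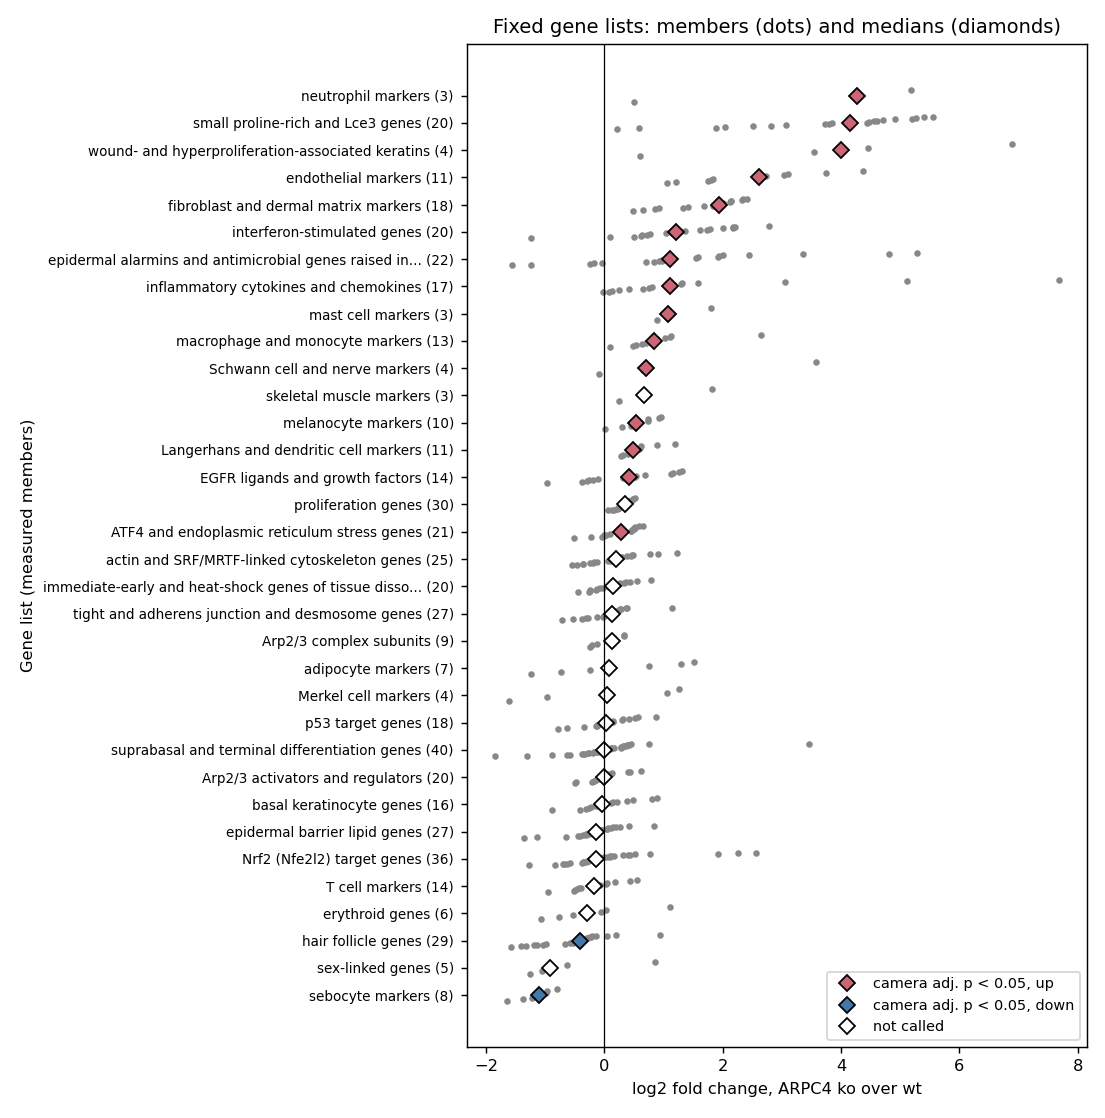
Log2 fold change of ARPC4 ko over wt for each measured member (grey dots) of the 34 fixed gene lists and each list's median (diamonds), with the number of measured members in parentheses and the lists that camera called filled in red when higher and in blue when lower. The 15 lists called higher run from a median of 0.28 for the ATF4 list to 4.28 for the neutrophil list, and the 2 called lower are the hair follicle and sebocyte lists, at -0.42 and -1.10.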

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

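The reassignment of basal gene levels and the tests of collection, of keratinocyte share, of dermal tissue and of neutrophils were chosen after the results were seen, and only for the splits of the samples and the reassignment was the outcome that would fit written down before they were run.

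Reads that were not assigned to a gene were compared between the groups as a percentage of all reads listed, by class and chromosome. Of 63 such shares 7 were higher in every ko library than in every wt library and 1 was lower, where chance gives 5% in each direction. Reads with more than 1 alignment on chromosome 15, which carries the Krt6 genes, made up 0.921% in ko against 0.498% in wt, and those on chromosome Y 0.00952 against 0.00703%. Reads outside genes made up 0.0357 against 0.0318% on chromosome 11, 0.0195 against 0.0175% on chromosome 15, 0.0161 against 0.0149% on chromosome 5 and 0.00823 against 0.00662% on chromosome X. Ambiguous reads on chromosome 4 made up 0.0228 against 0.0188%. The 1 lower share was that of ambiguous reads on chromosome 6, which carries Arpc4, at 0.0118% in ko against 0.0162% in wt. Which genes those reads overlapped is not given. With groups of 3 no single library was tested as an outlier.

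The first pattern is that 30 genes passed the test with edgeR, while 772 did with the basal gene level as a covariate. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many calls. It gave 30 against at most 5 in any other split, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 1814 genes, which is not the highest count. The split of wt replicates 1 and 2 with ko replicate 1 gave 1824, and that of wt replicates 1 and 3 with ko replicate 3 gave 2203. Different shares of basal and suprabasal cells between libraries are a candidate source of the spread that limits the calls. The true basal values gave 772 calls. Of the 36 reassignments of these values within groups, 1 (the true one) gave as many, with 691 the highest of the others. These values come from the same counts, lowest in wt replicate 2 and highest in ko replicate 3, the ends of the first principal component. Such a covariate takes up much of the spread whatever its source, so the count does not show that cell shares are the source. A difference between dated and undated collections cannot be told apart from different cell shares. The dated wt libraries lay 2.43 log2 apart in basal genes and the undated one 0.5 from the nearer of them, while in ko these gaps were 0.27 and 1.61. In other measures the undated libraries stood apart in both groups. Chromosome 3 reads with more than 1 alignment made up 15.9% (wt) and 18.9% (ko) of their reads, against 24.2 to 28.5% in the dated ones. Mitochondrial genes held 1.395% (wt) and 1.428% (ko) of their gene counts, against 1.0 to 1.144%.

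The second pattern is that endothelial and fibroblast markers were higher in ko. A lower share of keratinocytes would raise the markers of every other cell type alike, but the endothelial list moved 2.43 log2 (SE 0.33) more than the T cell list, and the sebocyte list moved by -1.14 (SE 0.24). More dermal tissue in the ko preparations may account for both lists, since all 18 fibroblast markers were above 0 and the lists moved by amounts 0.48 log2 (SE 0.26) apart. A gap within 2 SE does not show that the lists moved alike. Their mean fitted log2 fold changes were 2.48 for the endothelial and 1.70 for the fibroblast markers. Postn stood at 167.6 ± 116.7 CPM in wt and 841.6 ± 793.1 CPM in ko, 12 of the 18 fibroblast markers reached 5 CPM in wt, and no marker is in another list. Whether vessels or matrix genes change in the ko animals themselves was not tested and stays open.

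The third pattern is that Cxcr2 was higher in ko. Neutrophils in the ko epidermis would bring their other abundant transcripts, but the median of 5 mature neutrophil markers was 6 reads over the ko libraries together, against 578 for Cxcr2. The highest of these markers had 9.71, 1.79 and 8.37% of the Cxcr2 reads in ko replicates 1 to 3. That argues against neutrophils as the source of Cxcr2, and it does not decide the source of S100a8 and S100a9. No other cell source was tested.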

How the results depend on the processing

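The basal and sex covariates and leaving out both end libraries were chosen after the results were seen. Counts are genes changed, then higher and lower in ko, against 30, 30 and 0, and the cause of each shift was not tested. By scaling and filter there were 19, 19 and 0 with total counts only (17 of the 30 kept), 57, 55 and 2 without a filter on low counts, and 18, 18 and 0 with 1 CPM in 3 libraries. By test there were 650, 431 and 219 with DESeq2 and its own filter on low counts (617, 398 and 219 among the genes tested with edgeR), 0 with limma-voom (1748 at an unadjusted p under 0.05), 18, 18 and 0 with the older quasi-likelihood fit, and 0 with edgeR at a threshold of 0.01 (1814 at an unadjusted p under 0.05). By design there were 709, 438 and 271 with the collection covariate, 227, 160 and 67 with the dated libraries, 772, 502 and 270 with the basal covariate, 62, 57 and 5 with the sex covariate, and 294, 166 and 128 without both end libraries. Leaving out 1 library gave 0 to 64 changed, 0 to 64 higher and 0 to 2 lower, with 0 without wt replicate 1, 2 or 3 or ko replicate 2, 2 lower without ko replicate 1 and 64 without ko replicate 3. DESeq2 and upper-quartile scaling, a fit that was not robust and a 2-fold minimum gave 26 to 30. The replicate block gave 354, 254 and 100, but not every same-numbered pair of libraries deviated together (correlations of -0.19, 0.47 and 0.67 for replicates 1 to 3), and wt replicate 2 correlated better with ko replicate 1 (0.51) than with its own number; under the block the growth factor list lost its call (adjusted p = 0.06) and the proliferation list gained one (0.33, adjusted p = 0.0155). Of the 17 named genes called, every one was higher in ko wherever it had a value. Arpc4 stayed between -0.28 and -0.13 with an adjusted p from 0.234 to 0.766. The Nrf2 list stayed between -0.21 and -0.02 and uncalled, with an adjusted p from 0.122 to 0.694. The alarmin list stayed called (1.0 to 1.47) except with an estimated correlation (1.1, adjusted p = 0.201). The direction given by camera, not always the sign of the median, reversed in called results for the basal list without wt replicate 2 (-0.52), whose range over single libraries left out was -1.07 to 0.61, and, without both end libraries, for the suprabasal (0.35), basal (-1.54), lipid (0.28), proliferation (-0.71) and adipocyte (1.43) lists. Single genes uncalled on both sides changed sign in 96 comparisons, which count below as keeping their side. Over all comparisons, single genes kept their side of the threshold in 3783 cases, gained a call in 208 and lost one in 108, and lists did so in 644, 14 and 46. The older and the not robust fits give no list test. The median log2 fold change of all genes lay between -0.02 and 0.02 under every scaling. Depth limits genes of under 1 CPM, such as Lce3a, and most neutrophil markers.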

Other observations

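The genes of this part were chosen after the results were seen. With the dated or undated title as a covariate, 252 genes of at least 5 CPM with groups that did not overlap were higher in ko and 167 lower (edgeR quasi-likelihood, Benjamini-Hochberg). Predicted genes, sex-linked genes and genes without a symbol were left out of these counts. Among the higher ones the hyaluronan synthase Has3 stood at 4.00 ± 1.88 CPM in wt and 33.9 ± 19.7 CPM in ko (log2 fold change 3.01, SE 0.32, adjusted p = 0.00965 in that fit), and the retinaldehyde dehydrogenase Aldh1a3 gave 3.2 (SE 0.43, adjusted p = 0.0221). Il33 (3.14, adjusted p = 0.0334), Krt6a (3.61, adjusted p = 0.033) and Rptn (3.39, adjusted p = 0.042) also passed there.

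Among the lower ones in the same fit the acyl-CoA synthetase Acsl6 stood at 77.8 CPM in wt and 17.8 CPM in ko (-2.17, SE 0.30, adjusted p = 0.0221), and the sebaceous desaturase Scd3 (-1.66, adjusted p = 0.0285), the reductase Far2 (-1.40, adjusted p = 0.0297) and the hydroxylase Fa2h (-1.38, adjusted p = 0.0478) were lower as well. The receptors Mrgprb2 (-1.80, SE 0.30, adjusted p = 0.0291) and Mrgprb3 (-1.75, SE 0.20, adjusted p = 0.00994) were also lower. These genes did not pass the test without the covariate.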
